A study of Mus musculus with 12 samples.

How the data were processed

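Histone marks were profiled in E14TG2a mouse embryonic stem cells, a male line grown here in serum medium with LIF and the inhibitors PD0325901 and CHIR99021. Cells were either wild type (WT) or carried a deletion of the C-terminal intrinsically disordered region of ALKBH5 (del-cIDR). H3K4me3 and H3K27ac were profiled by CUT&Tag and H3K9me3 by CUT&RUN, 2 methods that cut or tag chromatin where an antibody is bound, with commercial kits. Each of the 3 marks has 2 libraries per genotype, 12 libraries in all. The labels do not say whether the 2 replicates of a group came from separate cultures or clones. The permutation p-values therefore measure the spread between these libraries, which may be technical.

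Per the submitters' processing notes, the tools used were fastp, BWA, SAMtools, Picard, MACS2 and featureCounts, and the genome build was GRCm39. Versions, order and settings are not given in the sources used here, nor is whether a control library entered the peak calls. The authors deposited 1 peak list per library, so peaks were called per sample. H3K4me3 and H3K27ac came as narrow peaks and H3K9me3 as broad peaks. For each peak the deposited lists give a fold enrichment, a ratio over the background expected in that library, and the −log10 of its p-value and q-value. The weakest deposited peak had a −log10 q of 1.30 in the H3K27ac lists and 1.00 in the H3K9me3 lists, which are q-values of 0.05 and 0.1, so sites under those limits are not in the lists. Fold and −log10 values are the authors' own, made within a library. They were used only to describe, rank or filter peaks of the same list. Read depth is unknown, because the lists hold no read counts. A longer list can come from a deeper or cleaner library, and no interval for counting error could be given.

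Comparisons used the peaks on chromosomes 1 to 19, X and Y. Peaks on the mitochondrial genome, on unplaced sequences and on a sequence named dm were left out and counted separately. For each mark, peaks of the 4 libraries that overlapped by at least 1 bp were merged into regions. A region was called only in a genotype when both libraries of that genotype had a peak in it and neither library of the other had one. An exact permutation test of 2 libraries against 2 gives no p-value below 0.333, and no parametric test was used, so each count was set beside the same count for the 2 other ways to part 4 libraries into pairs, each of which mixes the genotypes. Peak numbers and covered lengths were compared with exact permutation tests, two-sided. Overlaps between marks were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment within each family. Regions are not independent replicates, so these p-values describe the regions of these libraries. The overlap of 2 lists in bases is given as the Jaccard index, the shared bases over the bases in either list.

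The share of peaks on each chromosome was tested after the data had been seen. The log2 ratio of shares, del-cIDR over WT, was averaged over the 3 marks. Genotype labels were permuted within each mark, which gives 216 arrangements and a smallest p of 0.00926. This counts the 3 marks as separate experiments. A property of 1 cell population would recur in every mark, so these p-values are smaller than a test of 2 libraries against 2 allows. Adjustment was over 21 chromosomes. Shares were also computed in bins of 10 Mb. On chromosomes X, 6, 8 and 12 a change point between bins was placed from H3K4me3 and H3K27ac. For regions found in all 4 libraries of a mark, the fold was ranked within each library among those same regions, so that ranks could be set side by side. All coordinates are GRCm39 and count from 1.

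The gene table at hand was built on GRCm38.p6, another build, and no genome was used here. Peaks were therefore not assigned to genes. The planned comparisons of genes marked in a single genotype, the tests of 19 gene lists and the values at named genes were not made. The rule for named items, fixed before the data were examined, was kept for regions. Per mark and direction it takes the 12 regions with the highest mean percentile of fold within their own 2 lists. The comparison of H3K4me3 with H3K27ac, planned over genes, was made over overlapping regions. Regions outside this rule that the text names were chosen after their values were seen.

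Alternatives fixed before the data were examined were a minimum −log10 q of 5, the same minimum in both libraries of a genotype with no peak at all in the other pair, lists cut to the length of the shortest list of the mark by −log10 p, peaks covering at least 50% of the region, merging within 1000 bp, leaving out each library, and a fit paired by replicate number. The shortest lists held 19033 H3K4me3, 23407 H3K27ac and 21705 H3K9me3 peaks. Leaving out chromosomes X, 6, 8 and 12 and all alternatives for chromosome shares and for overlaps between marks were added after the data had been seen, as were the split of H3K4me3 regions by the median fold of their lists, the counts and tests of genotype-specific regions by chromosome and the comparison of the densest 1-Mb windows. The code that calls regions was tested on simulated data. In 16093 H3K4me3, 13460 H3K27ac and 14460 H3K9me3 regions with 200 planted changes per direction, made by removing peaks, 100% were recovered with 0 false calls. This checks the code and gives no error rate, since the simulated lists lack the variation between libraries that the mixed splits show. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.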

Results

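Histone marks were compared between WT mouse embryonic stem cells and cells in which ALKBH5, an enzyme that removes N6-methyladenosine from RNA, lacked its C-terminal disordered region. The series addresses whether such regions restrain where demethylases act on the genome, and these libraries show the histone marks in the mutant. H3K4me3 marks active promoters, H3K27ac active promoters and enhancers, and H3K9me3 heterochromatin and silenced repeats. On the assembled chromosomes the 4 H3K4me3 lists held 19033 to 19881 peaks with a median width of 968 to 988 bp. The 4 H3K27ac lists held 23407 to 33460 peaks with a median width of 545 to 596 bp. The 4 H3K9me3 lists held 21705 to 43785 peaks with a median width of 363 to 730 bp, and WT replicate 1 had both the fewest and the narrowest.

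Most H3K4me3 regions were shared by both genotypes. Of 23623 regions, 16093 (68.1%) had a peak in all 4 libraries. There were 491 regions with a peak in both del-cIDR libraries and neither WT library, and 671 with the opposite pattern. These genotype-specific regions were weak sites. Their median fold lay at the 14.3th percentile of the del-cIDR lists and the 16.4th percentile of the WT lists, against the 57.9th percentile for regions found in all 4 libraries. None of the 491 or 671 reached the 90th percentile, which 1772 of the shared regions did. Regions that parted the libraries in the mixed ways were weak too. Below the median fold of their lists lay 194 of 198, 276 of 282, 220 of 226 and 238 of 239 of them, beside 487 of 491 (del-cIDR only) and 650 of 671 (WT only). Weakness was therefore not particular to the genotype split. Domains chosen for being wide in all 4 libraries included 11:3238837-3243190, with 4035 to 4194 bp under peaks in each library, and 17:34336520-34340812, with 4027 to 4293 bp.

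Among the H3K4me3 regions called only in WT, most of the strongest overlapped H3K9me3 in at least 1 library. The leading one, 1:3124672-3125410, had a fold of 14.8 and 12.4 in the WT libraries and an H3K9me3 peak in all 4 H3K9me3 libraries. The next, 4:64786258-64786887, had folds of 12.2 and 11.2 and an H3K9me3 peak in both del-cIDR libraries and neither WT library. Another, 2:83259984-83261234, had folds of 9.83 and 13.9 and H3K9me3 in 3 libraries. Of the 12 strongest WT-only regions 11 overlapped an H3K9me3 region, against 3 of the 12 strongest del-cIDR-only regions, with a peak in any of the 4 H3K9me3 libraries counted. Of those 11, H3K9me3 was found in all 4 libraries at 2 and in a single library at 3. The 2 sets differed in strength, the weakest of each being at the 65.0th percentile of fold in WT and the 43.1th in del-cIDR. At or above the median fold of the lists, 17 of 21 WT-only and 2 of 4 del-cIDR-only regions overlapped H3K9me3, a difference that did not pass (exact p = 0.234). The strongest del-cIDR-only region, 9:123290865-123291228, had folds of 11.6 and 10.9, H3K27ac in all 4 libraries and H3K9me3 in 3. Over all genotype-specific H3K4me3 regions, 9.54% of the WT-only and 5.91% of the del-cIDR-only regions overlapped H3K9me3 (Fisher's exact test, odds ratio 0.595, p = 0.0282, adjusted p = 0.0424 over 6 tests), against 1.62% of the regions in all 4 libraries. In the mixed pairs the share was 2.53% to 5.75%. The difference missed 0.05 when peaks within 1000 bp were merged (exact p = 0.0759).

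The number of H3K4me3 peaks was 19256.5 ± 316 in del-cIDR and 19779 ± 144 in WT (SD, n = 2 each, exact permutation p = 0.333, the smallest this test gives for 2 against 2). Covered length was 20.1 ± 0.548 Mb and 20.4 ± 0.250 Mb (SD, n = 2 each, exact permutation p = 0.667). Pairs of libraries shared 79.6% of their bases within del-cIDR and 78.9% within WT, and 76.5% to 76.6% between genotypes. The 1162 genotype-specific regions were 2.42 and 2.50 times the 480 and 465 regions that parted the libraries in the 2 mixed ways. At equal list lengths the counts were 565 and 538, so the excess of WT-only over del-cIDR-only regions did not hold. With any 1 of the 4 libraries left out, which by construction lets more regions qualify, the counts were 888 to 1420 in del-cIDR and 1073 to 1782 in WT, and with a −log10 q of at least 5 in both libraries of a genotype they were 143 and 202.

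For H3K27ac, 3238 regions were called only in del-cIDR and 922 only in WT, and 13460 of 50439 regions (26.7%) were found in all 4 libraries. The strongest del-cIDR-only region was 6:33036511-33037310, with folds of 17.8 and 16.4 in the del-cIDR libraries, and it carried H3K4me3 in all 4 H3K4me3 libraries. The region 9:88948639-88949455, with folds of 12.6 and 11.3, and 3:55884277-55885013, with folds of 10.8 and 9.76, also lay at H3K4me3 sites of all 4 libraries. In contrast 18:84643573-84643900, with folds of 10.2 and 12.4, had no other mark. Chromosome 8 carried del-cIDR-only regions at 20051643-20052107, with folds of 8.39 and 9.72 and H3K9me3 in both WT libraries and neither del-cIDR library, and at 20137819-20138525, with H3K9me3 in all 4. In WT, the strongest region was 18:59863240-59863521, with folds of 12.04 and 14.2 and no other mark. It was followed by 3:106580037-106580903, with folds of 8.96 and 8.10 and H3K4me3 in all 4 libraries.

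H3K27ac regions specific to del-cIDR lay at H3K4me3 sites more often than those specific to WT, 39.2% against 18.8% (Fisher's exact test, odds ratio 2.79, adjusted p = 5.71e-32), with 62.3% for regions in all 4 libraries and 22.1% to 31.3% in the mixed pairs. At equal list lengths the shares were 47.9% and 20.7%. With 1 library left out both sets grow by construction, and the genotype with a single library also takes in unreplicated peaks. Its share was lower each time, and whether those peaks lowered it was not tested. With replicate 1 of del-cIDR left out the shares were 24.4% and 21.0%, and with replicate 2 left out they were 24.2% and 25.2%, in the reverse order. With replicate 1 of WT left out they were 42.4% and 12.8%, and with replicate 2 left out 43.5% and 11.9%. Overlap with H3K9me3 was found for 3.27% of the del-cIDR-only and 7.05% of the WT-only regions (Fisher's exact test, adjusted p = 5.53e-06). It was 3.74% for regions in all 4 libraries and 3.60% to 4.07% in the mixed pairs, so the WT-only share was the one that stood apart. Without WT replicate 1 the del-cIDR-only and WT-only shares were 3.65% and 4.001%, and without WT replicate 2 they were 3.64% and 4.44%. The WT-only sets then held 4649 and 6009 regions in place of 922, most of them unreplicated, so these shares do not test the replicated set.

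The del-cIDR lists of H3K27ac were longer, with 31156.5 ± 3258 peaks against 24605.5 ± 1695 (SD, n = 2 each, 1.27-fold, exact permutation p = 0.333). They covered 21.6 ± 1.61 Mb against 16.4 ± 1.77 Mb (SD, n = 2 each, exact permutation p = 0.333). Bases were shared at 49.1% within del-cIDR, 44.2% within WT and 40.9% to 43.4% between genotypes. The total of 4160 genotype-specific regions compares with 1870 and 1884 in the mixed splits. With lists cut to equal length the counts were 1846 and 1303, a total of 3149 against 1581 and 1518, and the ratio of del-cIDR-only to WT-only fell from 3.51 to 1.42. With any 1 of the 4 libraries left out, the counts were 4979 to 12273 in del-cIDR and 1456 to 6009 in WT, and with a −log10 q of at least 5 in every library they were 2747 and 347, a ratio of 7.92.

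**Figure D1:**
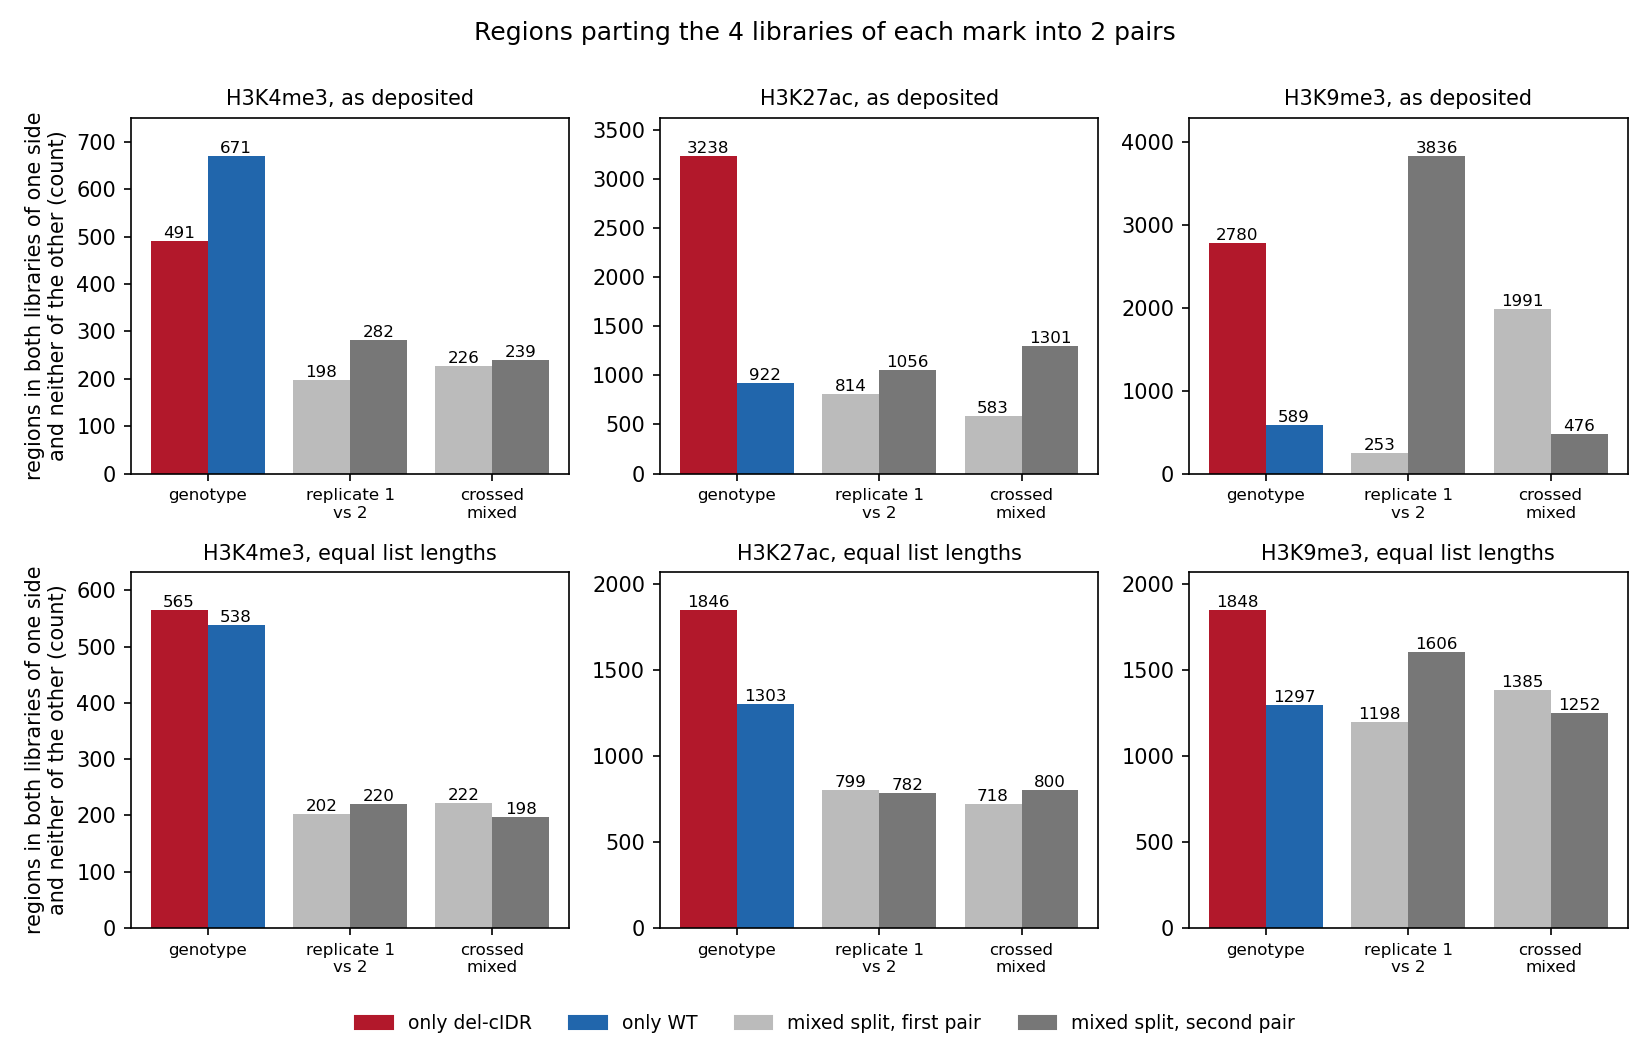
Bars give the number of merged regions with a peak in both libraries of a pair and in neither library of the other pair, for the genotypes and for the 2 mixed splits of the same 4 libraries, with the lists as deposited (top) and cut to equal length (bottom). In H3K4me3 and H3K27ac the genotype split gives more regions than either mixed split, and in H3K9me3 as deposited one mixed split gives 3836 regions on one side, more than the 2780 called only in del-cIDR.

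Of the 20 1-Mb windows densest in H3K9me3 found separately in each genotype 14 were the same, while single libraries shared 17 within del-cIDR, 9 within WT and 9 to 15 between genotypes. Among windows chosen for being dense in all 4 libraries, those starting at 146 and 147 Mb of chromosome 4 held 33.5 to 47.1 kb and 32.6 to 75.0 kb under peaks, and others lay at 18 and 20 Mb of chromosome 12 and at 66 and 68 Mb of chromosome 13. Domains wide in all 4 libraries included 9:123728000-123734316, with 4144 to 5516 bp under peaks, and 4:145170777-145176677, with 2800 to 5110 bp. Of 61706 regions, 14460 (23.4%) were found in all 4 libraries, 2780 only in del-cIDR and 589 only in WT. At equal list lengths they were 1848 and 1297, and the ratio fell from 4.72 to 1.42. The strongest del-cIDR-only region was 6:135443041-135443227, with folds of 15.5 and 21.1, followed by 1:118667403-118667616, with folds of 7.44 and 7.63. The strongest WT-only region was 14:17598661-17598926, with folds of 7.25 and 6.64. At the second, X:169088627-169088830, both del-cIDR libraries and neither WT library had H3K4me3. The 12 leading regions were short, with a median width of 204 bp in del-cIDR and 184.5 bp in WT.

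The 3369 genotype-specific H3K9me3 regions lay between the 2 mixed splits of the same libraries, which gave 4089 and 2467. At equal list lengths 3145 were above both, at 2804 and 2637. With a −log10 q of at least 5 the counts were 112 in del-cIDR and 17 in WT, and with any 1 library left out 3417 to 11815 and 1089 to 11276. Peak number was 38753.5 ± 2811 in del-cIDR and 32745 ± 15613 in WT (SD, n = 2 each, exact permutation p = 1), and covered length 30.9 ± 6.05 Mb and 20.5 ± 14.7 Mb (SD, n = 2 each, exact permutation p = 0.667). WT replicate 1 covered 10.1 Mb and WT replicate 2 30.9 Mb. Without WT replicate 1 the log2 ratio of peak number went from 0.24 to -0.18, with fewer peaks in del-cIDR, and that of covered length from 0.59 to 0.0034. Without WT replicate 2 they were 0.84 and 1.61. Bases were shared at 40.4% within del-cIDR, 20.9% within WT and 20.2% to 40.5% between genotypes.

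Where H3K4me3 and H3K27ac were both genotype-specific, they mostly went the same way. Genotype-specific regions of the 2 marks overlapped in 74 pairs, and 61 of them (82.4%) had the same direction, 45 in del-cIDR and 16 in WT (Fisher's exact test, odds ratio 24.0, p = 4.46e-07, adjusted p = 1.34e-06 over the 3 pairs of marks). Of the others, 10 had H3K4me3 only in WT and H3K27ac only in del-cIDR, and 3 the reverse. The mixed splits gave only 8 and 12 pairs, and their sides do not match between marks, so they give no share to compare. Sites that held both marks only in del-cIDR included X:133987732-133988370, with H3K4me3 folds of 9.05 and 7.21 and H3K27ac folds of 6.45 and 7.89, and 10:83623221-83624927, with H3K4me3 folds of 7.65 and 9.75 and H3K27ac folds of 7.90 and 5.61. Sites that held both only in WT included X:47522216-47522849, with H3K4me3 folds of 5.74 and 7.77, and 6:24673356-24673831, with 8.19 and 9.55. No such relation was detected for H3K9me3, over few pairs. With H3K4me3, 2 of 9 pairs had the same direction (exact p = 0.167), and with H3K27ac, 12 of 20 (exact p = 0.617).

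The X chromosome held a larger share of the peaks in del-cIDR than in WT in all 3 marks, and chromosomes 6, 8 and 12 a smaller share. For H3K27ac, X held 3.29% ± 0.0464 of the peaks in del-cIDR and 2.48% ± 0.00136 in WT (SD, n = 2 each), a log2 ratio of 0.41. For H3K4me3 the shares were 3.47% ± 0.0164 and 3.15% ± 0.0307 (SD, n = 2 each, log2 ratio 0.14), and for H3K9me3 6.94% ± 0.0860 and 4.39% ± 1.34 (SD, n = 2 each, log2 ratio 0.69). The WT replicates of H3K9me3 had 3.44% and 5.34%, and without replicate 1 the log2 ratio was 0.38 on X and -0.16 on chromosome 8. Chromosome 6 had log2 ratios of -0.09 in H3K4me3, -0.23 in H3K27ac and -0.20 in H3K9me3, chromosome 8 of -0.07, -0.12 and -0.28, and chromosome 12 of -0.09, -0.23 and -0.16. On these 4 chromosomes both del-cIDR libraries lay on the same side of both WT libraries in each mark. Each gave an exact permutation p of 0.00926, the smallest of the 216 arrangements (adjusted p = 0.0486 over 21 chromosomes). These values rest on counting the 3 marks as separate experiments. Among the other 17 chromosomes the lowest was p = 0.0185 by exact permutation, adjusted to 0.0778. The median −log10 q was 1.65 to 1.97 in the H3K9me3 lists, so a minimum of 5 removed most of their peaks. With that minimum none of the 4 chromosomes passed after adjustment, and chromosome 12 went to a mean log2 ratio of 0.08. There H3K4me3 and H3K27ac kept their direction in every pair of libraries on all 4 (X 0.15 and 0.50, 12 -0.03 and -0.13), while pairs of H3K9me3 libraries went both ways on X, 6 and 12 (means 0.14, 0.11 and 0.40). With either H3K9me3 library of del-cIDR left out, the 4 chromosomes no longer passed after adjustment, while with any other library left out they did. The number of arrangements is the same whichever library is left out, so it does not account for this. Without either of these H3K9me3 libraries the mean log2 ratios hardly moved (0.42 and 0.41 on X, -0.17 on 6, -0.16 on 8 and 12).

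**Figure D2:**
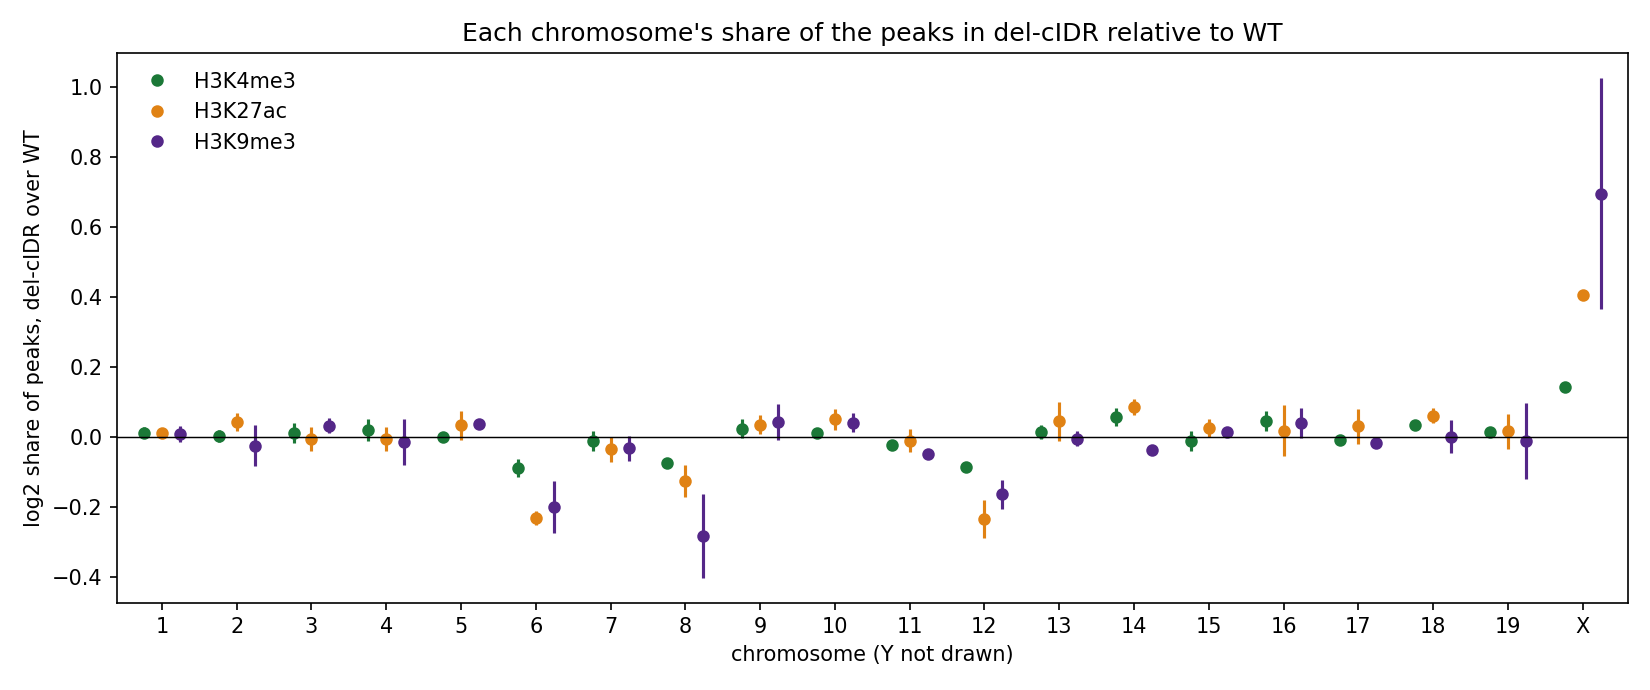
Points give the log2 ratio of each chromosome's share of the peaks, del-cIDR over WT, for the 3 marks, and lines run from the lowest to the highest ratio of a del-cIDR library to a WT library (2 libraries per genotype). Chromosome X lies above 0 in all 3 marks, at 0.14, 0.41 and 0.69, and chromosomes 6, 8 and 12 lie below 0.

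Change points were placed from the H3K4me3 and H3K27ac bins, so the contrast of these marks between the sides of a point is partly set by that choice. On X the H3K4me3 and H3K27ac difference lay distal to 80 Mb. There the log2 ratio was 0.26 in H3K4me3, 0.68 in H3K27ac and 0.83 in H3K9me3, and all 9 bins of 10 Mb were above 0 in each mark. Proximal to 80 Mb it was 0.005 in H3K4me3 and -0.012 in H3K27ac. In H3K9me3 it was 0.53 there, with 2.84% ± 0.0696 of the peaks in del-cIDR (SD, n = 2), 1.497% in WT replicate 1 and 2.59% in WT replicate 2. On chromosome 12 the log2 ratios distal to 40 Mb were -0.11, -0.37 and -0.22 in H3K4me3, H3K27ac and H3K9me3, and proximal to it -0.02, 0.04 and -0.08. Chromosome 6 was lower on both sides of its change point at 20 Mb, with -0.19, -0.27 and -0.08 proximal and -0.08, -0.23 and -0.22 distal in H3K4me3, H3K27ac and H3K9me3. On chromosome 8, in the same order, the values were -0.03, -0.08 and -0.28 proximal to 50 Mb and -0.09, -0.15 and -0.28 distal to it. Proximal H3K4me3 pairs of libraries went both ways there (-0.064 to 0.0099). Genotype-specific regions on these chromosomes derive from the peaks by which the chromosomes were chosen, so tests of them are no separate evidence. Of 12 Fisher's exact tests of each chromosome against the others, 11 passed after adjustment, and H3K4me3 on chromosome 8 did not (adjusted exact p = 0.158). On X, 33 H3K4me3 regions were specific to del-cIDR and 13 to WT, 190 and 12 for H3K27ac, and 428 and 19 for H3K9me3. In the same order they were 21 and 56, 141 and 92, and 127 and 64 on chromosome 6, 22 and 44, 136 and 67, and 65 and 54 on 8, and 8 and 37, 96 and 60, and 73 and 47 on 12. Across 271 bins of the genome, which are not independent replicates, the log2 ratios of H3K4me3 and H3K27ac correlated with Pearson's r = 0.58 (Spearman's rho = 0.46), and those of H3K27ac and H3K9me3 with r = 0.55 (rho = 0.35). Without the 4 chromosomes r was 0.29 and 0.04.

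**Figure D3:**
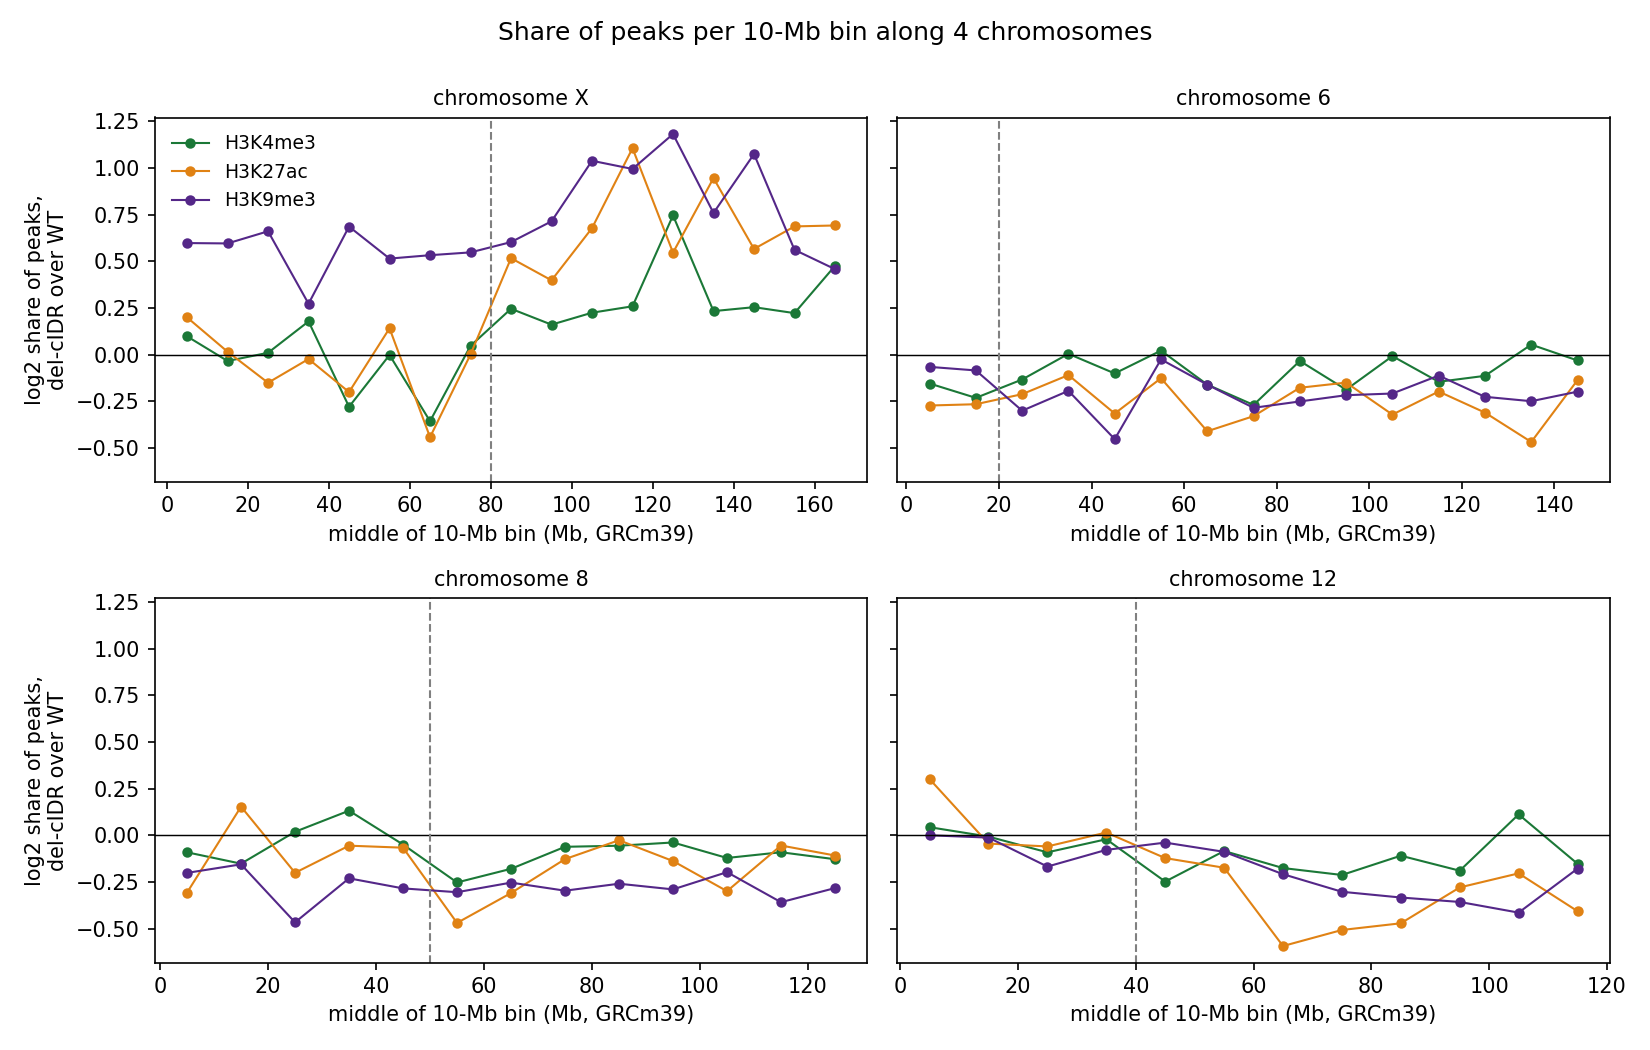
Lines give the log2 ratio of the share of peaks, del-cIDR over WT, in bins of 10 Mb along chromosomes X, 6, 8 and 12 (GRCm39), for the 3 marks, and the dashed line marks the change point placed from H3K4me3 and H3K27ac. On X all 9 bins distal to 80 Mb lie above 0 in each mark, while proximal to it H3K4me3 and H3K27ac scatter around 0.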

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

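The tests of copy number on chromosomes X, 6, 8 and 12 and the choice of these chromosomes came after the result was seen, and the tests with equal list lengths and without these chromosomes were written down before their results were seen.

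The shift of whole chromosome stretches between the genotypes is the pattern most worth following up. Lists of different lengths do not account for it, since at equal lengths the log2 ratio of the X share in H3K27ac was 0.44. A difference in copy number of a chromosome segment between the cell populations is a candidate explanation for H3K4me3 and H3K27ac on distal X. Regions found in all 4 libraries also ranked higher by fold there in del-cIDR (60.7 and 58.8 against 49.9 and 50.1 in H3K4me3, 73.3 and 70.4 against 57.8 and 57.1 in H3K27ac), with at least 8.69 percentile points between the genotypes. Such regions ranked lower by at least 2.15 points on chromosome 6 and 0.715 on distal chromosome 12, where replicates lay up to 2.21 and 4.38 points apart. In H3K27ac the genotypes also lay 2.20 points apart on proximal X and 1.81 on proximal chromosome 12, where its share hardly differed, though H3K4me3 ranks overlapped. Gaps of this size therefore cannot decide on copy number for chromosomes 6 and 12. On chromosome 8 both del-cIDR libraries ranked below both WT libraries in H3K4me3 (47.1 and 47.0 against 48.9 and 48.8) but the genotypes overlapped in H3K27ac, with a gap of -3.08 points, so copy number stays open there. For H3K9me3 on distal X, copy number predicted higher fold ranks in del-cIDR, but they were at least 19.97 points lower, the reverse of the prediction. On chromosome 6 the H3K9me3 ranks also ran against the share, by a much smaller 2.25 points. Whether fold ranks of this mark follow copy number is therefore not known, and the question is not settled. On proximal X, where the H3K9me3 share was higher, the H3K27ac log2 ratio was -0.012. The boundary was placed from H3K4me3 and H3K27ac, so this part was chosen for a small difference in them and the ratio cannot exclude copy number. The H3K9me3 share there was 2.84% in del-cIDR, 1.497% in WT replicate 1 and 2.59% in WT replicate 2. Fold ranks come from the same libraries as the shares and do not tell copy number from a regional effect of the ALKBH5 deletion itself. Such an effect was not tested and stays open for all of these patterns, since genotype and cell population coincide.

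The excess of H3K27ac regions called only in del-cIDR over those called only in WT may in part come from the longer del-cIDR lists, because the ratio of 3.51 fell to 1.42 at equal lengths. It rose to 7.92 with a −log10 q of at least 5, where the log2 ratio of list lengths also rose, from 0.34 to 0.54, and to 7.45 with that minimum in both libraries and no peak in the others. At equal lengths the total of 1846 and 1303 still exceeded the mixed splits, and whether depth, signal quality or the genotype lengthened the lists could not be tested from peak lists.

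The shared direction of genotype-specific H3K4me3 and H3K27ac regions was not explained by the shifted chromosomes, since 81.5% of the pairs went the same way without X, 6, 8 and 12. It was not explained by list lengths either, with 92.1% at equal lengths. A difference between the genotypes at these sites is a hypothesis that stays open, and no causes other than these 2 were examined. The 2 genotypes could also be cell populations that differ at these sites for other reasons, which was not tested.

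Each list also holds peaks outside the assembled chromosomes, which the comparisons do not use and for which there is no control. A sequence named dm, which the labels do not explain, had peaks up to position 143715104. It carried 359 to 872 peaks in the H3K4me3 lists, 6 to 22 in the H3K27ac lists and 6 to 12 in the H3K9me3 lists. The 359 were in H3K4me3 del-cIDR replicate 1, and the other H3K4me3 lists held 772 to 872. The mitochondrial genome carried 4 to 6 peaks in each list.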

How the results depend on the processing

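The alternatives for chromosome shares and for overlaps between marks, and leaving out chromosomes X, 6, 8 and 12, were chosen after the data had been seen. Of 193 alternative values 140 kept their direction and side of the threshold, or stayed within 1.5 times for a count. The concordance of H3K4me3 and H3K27ac kept both in all 11 alternatives run (70.2% to 92.1%), and no peak number or covered length could pass a threshold in the exact permutation test used, with 2 libraries per genotype. Depth is unknown and limits every count, because a site is listed only where it passed the authors' q limit. The comparisons by gene, by gene list and with windows around transcription starts were not run, for lack of an annotation of the same build. Where no cause is given, the cause was not tested.

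With each library left out, a single library stands for a genotype, so more regions qualify by construction. H3K4me3 counts were 888 to 1420 (del-cIDR only) and 1073 to 1782 (WT only), H3K27ac 4979 to 12273 and 1456 to 6009, and H3K9me3 3417 to 11815 and 1089 to 11276. The log2 ratio of H3K9me3 peak number was -0.18 to 0.84, negative without WT replicate 1, and that of H3K4me3 covered length -0.048 to 0.0078, positive without del-cIDR replicate 1. That of H3K9me3 covered length was 0.0034 to 1.61, the ends without WT replicates 1 and 2. With a −log10 q of at least 5, 2747 and 347 H3K27ac regions were specific to del-cIDR and WT, a ratio of 7.92, and 112 and 17 H3K9me3 regions to del-cIDR and WT. With that minimum in both libraries and no peak in the others, the counts for del-cIDR and WT were 143 and 202 (H3K4me3), 797 and 107 (H3K27ac), and 11 and 4 (H3K9me3), fewer by construction. At equal list lengths they were 1846 for H3K27ac in del-cIDR and 1848 and 1297 for H3K9me3, and with 50% of the region covered 4605 for H3K9me3 in del-cIDR. Without chromosomes X, 6, 8 and 12 all 6 counts stayed within 1.5 times.

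With a −log10 q of at least 5 the mean log2 ratio of shares was 0.26 on X, -0.080 on 6, -0.28 on 8 and 0.077 on 12, with adjusted exact p of 0.156 to 1. H3K4me3 and H3K27ac kept their directions there, and H3K9me3, most of whose peaks this minimum removed, went both ways between pairs of libraries on X, 6 and 12 (means 0.14, 0.11 and 0.40). With each library left out it was 0.31 to 0.52 on X, -0.20 to -0.15 on 6, -0.20 to -0.12 on 8 and -0.18 to -0.14 on 12, with adjusted exact p of 0.0389 to 0.146. In H3K9me3 alone it was 0.38 to 1.01 on X and -0.40 to -0.16 on 8, the weaker ends without WT replicate 1. The difference in overlap with H3K4me3 between the 2 sets of genotype-specific H3K27ac regions was -0.983 to 31.5 percentage points with each library left out, and that in overlap with H3K9me3 -3.68 to -0.354. Unreplicated peaks of the genotype with a single library enter its set there, and whether they move its share was not tested. For H3K4me3 regions over H3K9me3 it was -3.10 points when merging within 1000 bp.

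The groups share replicate numbers, but with 2 pairs and no label that ties them the numbers pair nothing. Paired by number, the mean log2 ratio of peak number was -0.04 in H3K4me3 (exact p = 0.5), 0.34 in H3K27ac (exact p = 0.5) and 0.33 in H3K9me3 (exact p = 1), and that of covered length -0.02, 0.40 and 0.79. The replicate block changed no direction, and 0.5 is the smallest p it allows.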

Other observations

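The H3K4me3 sites with the highest fold among those called only in WT mostly overlapped an H3K9me3 peak of at least 1 library, a pattern seen and counted after the data were examined. Among WT-only regions at or above the median fold of their lists, 17 of 21 (81.0%) overlapped an H3K9me3 region, and 10 of these had H3K9me3 in both del-cIDR libraries and 2 in both WT libraries (WT replicate 1 of H3K9me3 was the shortest list). Among regions found in all 4 libraries at or above the median, 139 of 9596 (1.45%) overlapped H3K9me3. In the mixed pairs, 0 of 4, 0 of 6, 1 of 6 and 0 of 1 regions at or above the median did. Only 4 del-cIDR-only regions reached the median, and 2 of them overlapped H3K9me3 (exact p = 0.234 against WT-only). Below the median the shares were 7.23% for WT-only and 5.54% for del-cIDR-only regions (exact p = 0.276), against 1.86% for regions in all 4 libraries. No explanation was tested, since repeats and genes were not assigned here.

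The Y chromosome carried 83 and 100 H3K9me3 peaks in del-cIDR and 63 and 263 in WT. As a share of the list this was 0.236% ± 0.0139 in del-cIDR (SD, n = 2), 0.290% in WT replicate 1 and 0.601% in WT replicate 2. The log2 ratio was -0.83, with every pair of libraries below 0 (-1.41 to -0.24), and that of WT replicate 1 to 2 was -1.05. In H3K4me3 and H3K27ac pairs went both ways, on few peaks. Over the 3 marks the mean was -0.39 (exact permutation p = 0.130, adjusted p = 0.222).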
